A study of Arabidopsis thaliana with 6 samples.

How the data were processed

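Gene expression in the Arabidopsis thaliana root meristem was profiled in 6 RNA-seq libraries, 3 from mock-treated and 3 from RGF1-treated seedlings. Per the labels' protocols, Col-0 seedlings carrying a GFP reporter named HYP2-GFP were grown on plates for 6 days, moved to liquid MS medium, and held for 1 h with water or with 100 nM RGF1 peptide. The meristematic zone was cut out under a fluorescence microscope by its GFP signal, and each RNA sample came from 20 root sections. The RNA integrity number was above 9.0 in the 6 samples. From each sample, 50 ng of total RNA was amplified to cDNA with an Ovation kit, 3 μg of cDNA was sheared, and 400 ng with a mean length of 400 bp went into the library. Amplification from little RNA adds spread to low counts, and without molecular identifiers the reads are not independent molecules, so the counting intervals and floors given here cover counting error only. The labels describe 3 RNA extractions per treatment and do not say whether these came from separate plates or days, so the p-values measure the spread between these samples, which may be partly technical.

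The values used here are the read counts per gene that the authors deposited, 1 table per library, with whole numbers that had not been normalised. The submitters' processing notes name TopHat2 2.1.1, HTSeq and DESeq2 and the build TAIR10, without the role or the settings of each tool. The annotation release, the treatment of reads that match several places and the use of strand are not given in the sources used here. Reads of overlapping genes on opposite strands may therefore not have been told apart, and near-identical copies may have lost or shared reads. Each table held 30424 genes, of which 8412 had 0 counts in the 6 libraries, and 0 rows that named no gene. Gene positions, symbols and product names were taken from the TAIR10.1 reference annotation, in which 30214 of the gene identifiers were matched. The remaining identifiers were those of the 88 chloroplast and 122 mitochondrial genes.

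The total counts were 8959505, 8976382 and 6451658 in Mock replicates 1 to 3 and 9495012, 7004292 and 5421243 in RGF1 replicates 1 to 3. A floor of 3 counts per library corresponded to 0.321, 0.336 and 0.470 CPM (library-size-normalised counts, scaled by TMM) in the Mock libraries and to 0.313, 0.440 and 0.565 CPM in the RGF1 libraries. No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom over genes was 20.7 for the closest pair, Mock replicate 3 and RGF1 replicate 3.

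RGF1 was compared with mock in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the default expression filter and the quasi-likelihood F test over the 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. The filter kept 16737 genes and left out 13687. Standard errors of log2 fold changes were derived from the F statistic. Where the Mock libraries held 0 counts of a gene, the fold was computed against the mean of the Mock floors of 3 counts per library and is a lower bound. Where they held 1 to 3 counts, the ratio of summed counts is given with an exact 95% counting interval. On simulated counts for the 16737 genes, with the means and library sizes of these samples and 50 genes changed at each size, the test recovered 6% of the 2-fold changes, 60% of the 4-fold changes, 84% of the 8-fold changes and 84% of the 16-fold changes, and 7 of its 124 calls were false. With the replicate block these values were 10%, 64%, 84% and 84%, with 13 false among 134 calls. The simulation held no replicate effect and took each gene's spread from the fit without the block. The block values therefore do not describe how the block performs on paired libraries. Changes near 2-fold were mostly below what the test without the block could detect.

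Genes named in the text followed a rule: among called genes whose 3 RGF1 libraries lay on one side of the 3 Mock libraries and whose higher group had a mean of at least 5 CPM, the 15 with the largest log2 fold change upward and up to 10 downward, plus RITF1 and, for each gene list, up to 4 members with the smallest p. A total of 78 genes passed the rule upward and 5 downward. The rule, the tests, most of the alternative settings and 28 gene lists holding 395 genes, 303 of them tested, were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry. In the simulation camera called the 1 changed list and 0 of the 27 unchanged ones. The simulated genes were drawn independently, so this does not test camera on lists whose members move together. The estimated correlation was 0.957 for the photosynthesis list. Near-identical copies were searched among transcripts with BLAST 2.17.0 at 95% identity over at least 100 bp.

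The groups share replicate numbers 1 to 3. Over 12290 genes with a mean log2 CPM above 3, the deviations from the group means correlated at 0.247, 0.288 and 0.386 between the Mock and RGF1 libraries of the same number. Between libraries of different numbers the correlations were -0.23 to -0.07. Deviations from a group mean sum to 0, so these negative values follow from the positive ones and add no support. With 3 libraries per group, the same-numbered matching could also be the closest by luck. The main fit, set before the data were examined, held no block, since the labels do not state a pairing. Its counts and p-values therefore ignore the replicate numbers. The block fit, given as an alternative, treats the numbers as pairing the samples, on the evidence of the data and not of the labels. The value with the replicate number as a block is printed where it changed a call or moved a count by more than 1.5 times. The biological coefficient of variation was 0.442 without the block and 0.376 with it.

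The alternatives tried were the RLE and upper-quartile factors, scaling by total counts, no low-count filter, a mean count of at least 10, DESeq2 1.42.0, limma voom, the replicate block, removal of organelle genes, offsets for GC content and transcript length with and without the block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. GC content and length were known for 99.1% of the tested genes. The block fit without each pair of libraries in turn, and the block fit scaled by total counts, were added after seeing the data.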

Results

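RNA-seq read counts were obtained from the dissected root meristematic zone of Arabidopsis seedlings after 1 h in medium with water, the mock treatment, or with 100 nM RGF1. RGF1 (Root meristem growth factor 1) is a secreted, sulfated peptide that is perceived by receptor kinases and maintains the root meristem. Each treatment had 3 libraries, and the total count per library ranged from 5421243 to 9495012. Expression values are CPM (library-size-normalised counts scaled by TMM), given as mean ± SD over 3 libraries, and positions refer to TAIR10.1. The series title links RGF1 to meristem size through reactive oxygen species, and the comparison asks which transcripts of the meristem differed after 1 h of the peptide.

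After 1 h of RGF1, the list of glutathione S-transferases rose, and single genes that rose from 0 to 6 counts in the Mock libraries together included IGMT2, NAC042, CYP71A12, GSTU12 and WRKY30. IGMT2, an indole glucosinolate O-methyltransferase, had 1 count in the Mock libraries together and 148 ± 30.2 CPM after RGF1 (n = 3), and the glutathione S-transferase GSTU12 went from 0.214 ± 0.371 to 216 ± 72.2 CPM (n = 3). In total 78 genes were higher and 5 lower after RGF1 (edgeR, adjusted p below 0.05), among 16737 tested, and 64 of the 78 were at least 4-fold higher. The 83 called genes separated the 3 RGF1 libraries from the 3 Mock libraries in CPM. Over the tested genes such a separation was seen in 7.30% upward and 6.18% downward, where chance gives 10% in both directions together. With the replicate block 208 genes were called higher and 94 lower, and DESeq2 called 234 and 81. Without RGF1 replicate 1 the counts were 39 and 1, without Mock replicate 2 they were 49 and 1, and without RGF1 replicate 3 they were 64 and 3.

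**Figure D1:**
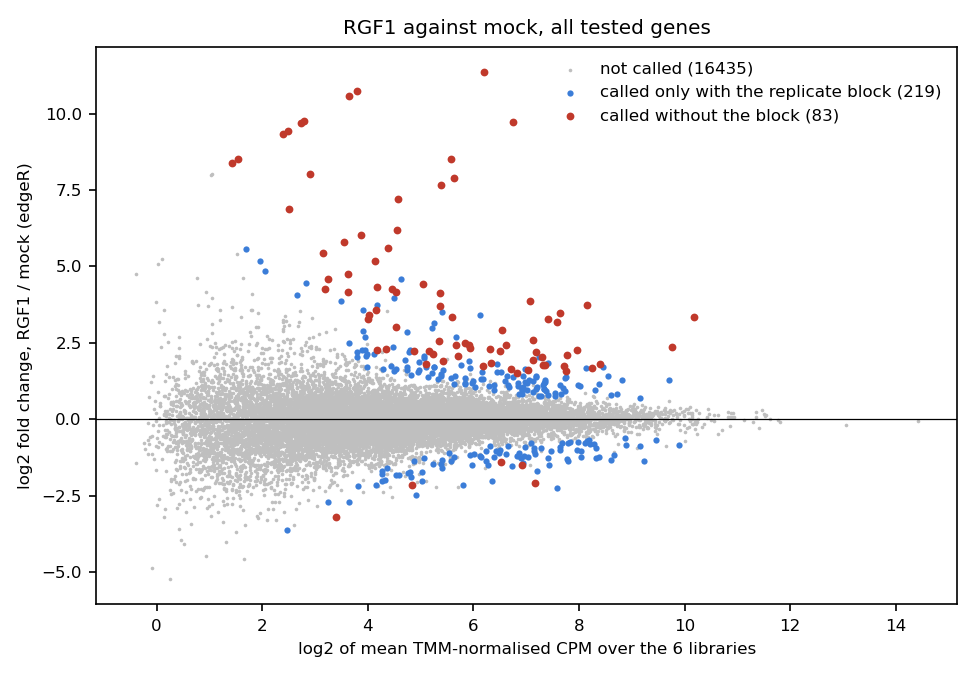
Log2 fold change (RGF1 over mock, edgeR) against the log2 of mean CPM over 6 libraries, 1 point per tested gene. Red points are the 83 genes called without the replicate block, 78 above 0 and 5 below, blue points the 219 called only with it, and grey points the rest; fitted folds of genes with 0 to 3 Mock counts depend on the prior count.

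Of the 15 named genes that rose, 8 had 0 counts in the 3 Mock libraries, so that their folds are lower bounds against a floor of 3 counts per library. AT4G08780 (chromosome 4, 5604105 to 5608290), a class III peroxidase, was at least 73.5-fold higher, at 27.6 ± 28.05 CPM after RGF1 (n = 3), with edgeR adjusted p = 0.00445. NAC042 (AT2G43000, chromosome 2, 17880457 to 17882636), a transcription factor of stress and camalexin responses, was at least 66.0-fold higher (edgeR adjusted p = 0.000633). The cytochrome P450 genes CYP71A12 (AT2G30750, chromosome 2, 13099486 to 13101371), which acts in indolic defence metabolism, and CYP72A8 (AT3G14620, chromosome 3, 4914789 to 4917176) were at least 36.9-fold and 35.4-fold higher, with edgeR adjusted p of 0.00735 and 0.00705. The tyrosine transaminase gene AT4G28420 (chromosome 4, 14055661 to 14057592) and the beta-glucosidase gene BGLU27 (AT3G60120, chromosome 3, 22205931 to 22209156) were at least 29.6-fold and 27.8-fold higher, with edgeR adjusted p of 0.0177 and 0.00891. The legume lectin gene AT1G53080 (chromosome 1, 19781288 to 19782352) was at least 15.6-fold higher (edgeR adjusted p = 0.0247). AT4G23250 (chromosome 4, 12162004 to 12167026), a cysteine-rich receptor-like kinase, was at least 14.3-fold higher with edgeR adjusted p = 0.0452. Several of these bounds rest on 1 library: without RGF1 replicate 1 those of AT4G08780, CYP71A12 and CYP72A8 fell to 30.7-fold, 19.2-fold and 21.5-fold, and without RGF1 replicate 3 those of AT4G28420, BGLU27 and AT4G23250 fell to 12.4-fold, 18.7-fold and 9.42-fold, with the call lost for each of these but AT4G08780. AT4G23250 overlaps AT4G23240 on the same strand, which had 0 counts. AT4G08780 overlaps AT4G08790 and NAC042 overlaps AT2G42990 on the opposite strand. AT2G42990 had 0 counts, and AT4G08790 had 176 counts in the Mock libraries and 271 in the RGF1 libraries.

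The other 7 named genes that rose had between 1 and 10 counts in the Mock libraries together. IGMT2 (AT1G21120, chromosome 1, 7395179 to 7396823) gave a count ratio of 3505 with an exact 95% interval of 629 to 138481, and its edgeR adjusted p was 6.75e-07. Its neighbour IGMT3 (AT1G21110, chromosome 1, 7389981 to 7391603) had a log2 fold change of 7.65 ± 0.65 (SE), with edgeR adjusted p = 0.000131. The transcripts of these 2 genes are 96.3% identical over 1359 bp, so that the division of reads between them is uncertain. GSTU12 (AT1G69920, chromosome 1, 26334250 to 26335630) and GSTF6 (AT1G02930, chromosome 1, 661088 to 662475) had log2 fold changes of 9.72 ± 0.67 and 7.89 ± 0.79 (SE), with edgeR adjusted p of 2.14e-05 and 0.000407. The fitted folds of these genes rest on few Mock counts, all or most of them in 1 library: without Mock replicate 1 the log2 fold change was 13.65 for GSTU12 and 9.98 for IGMT3, and without Mock replicate 2 it went from 7.89 to 12.53 for GSTF6 and from 11.35 to 13.11 for IGMT2. The calls held without these libraries, but the folds then depend on the prior count. Among the WRKY factors, which act widely in defence and senescence, WRKY30 (AT5G24110, chromosome 5, 8153115 to 8154710) went from 0.221 ± 0.224 to 94.7 ± 66.3 CPM (n = 3) and WRKY45 (AT3G01970, chromosome 3, 325952 to 327412) from 0.366 ± 0.634 to 47.2 ± 16.5 CPM (n = 3). Their edgeR adjusted p were 0.000131 and 0.00174, and their log2 fold changes of 8.53 and 7.20 ranged from 7.80 (without RGF1 replicate 3) to 9.38 (without Mock replicate 2) and from 6.55 (without Mock replicate 1) to 11.56 (without Mock replicate 3). WRKY41 (AT4G11070, chromosome 4, 6759098 to 6760794) had a count ratio of 357 with an exact 95% interval of 63.7 to 14161 and edgeR adjusted p = 0.00174. It overlaps AT4G11080 on the opposite strand, whose log2 fold change was 0.19. The log2 fold change of WRKY41 itself went from 8.01 to 9.90 without Mock replicate 3.

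The 5 genes that fell were expressed in the mock-treated meristem and fell less far. AT5G59350 (chromosome 5, 23940745 to 23943625), a gene of unknown function, went from 19.0 ± 4.29 to 2.098 ± 0.793 CPM (n = 3), a log2 fold change of -3.19 ± 0.55 (SE) with edgeR adjusted p = 0.0178. AT1G78260 (chromosome 1, 29446861 to 29450515), which encodes an RNA-binding protein, went from 46.8 ± 2.09 to 10.5 ± 3.98 CPM (n = 3; edgeR adjusted p = 0.0177). AT1G29025 (chromosome 1, 10124286 to 10127098), an EF-hand calcium-binding protein gene, went from 232 ± 96.6 to 53.8 ± 18.5 CPM (n = 3; edgeR adjusted p = 0.0163). The arabinogalactan protein gene AGP4 (AT5G10430, chromosome 5, 3277488 to 3278461) had a log2 fold change of -1.51 ± 0.28 (SE) with edgeR adjusted p = 0.0275. The receptor-like kinase gene AT2G02780 (chromosome 2, 781674 to 784944) had -1.40 ± 0.26 (SE) with edgeR adjusted p = 0.0339. AGP4 overlaps AT5G10435 on the opposite strand, which had 0 counts. Of the 20 named genes, 2, 8 and 4 lost the call without Mock replicates 1, 2 and 3, and 9, 5 and 7 without RGF1 replicates 1, 2 and 3. With limma voom 7 lost it, namely AT4G08780, CYP71A12, CYP72A8, AT4G28420, WRKY30, AT4G23250 and AT5G59350, with voom adjusted p from 0.0659 to 0.127. AT4G23250 also lost it when scaled by total counts (edgeR adjusted p = 0.0546) and with a mean count of at least 10 (0.0573).

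**Figure D2:**
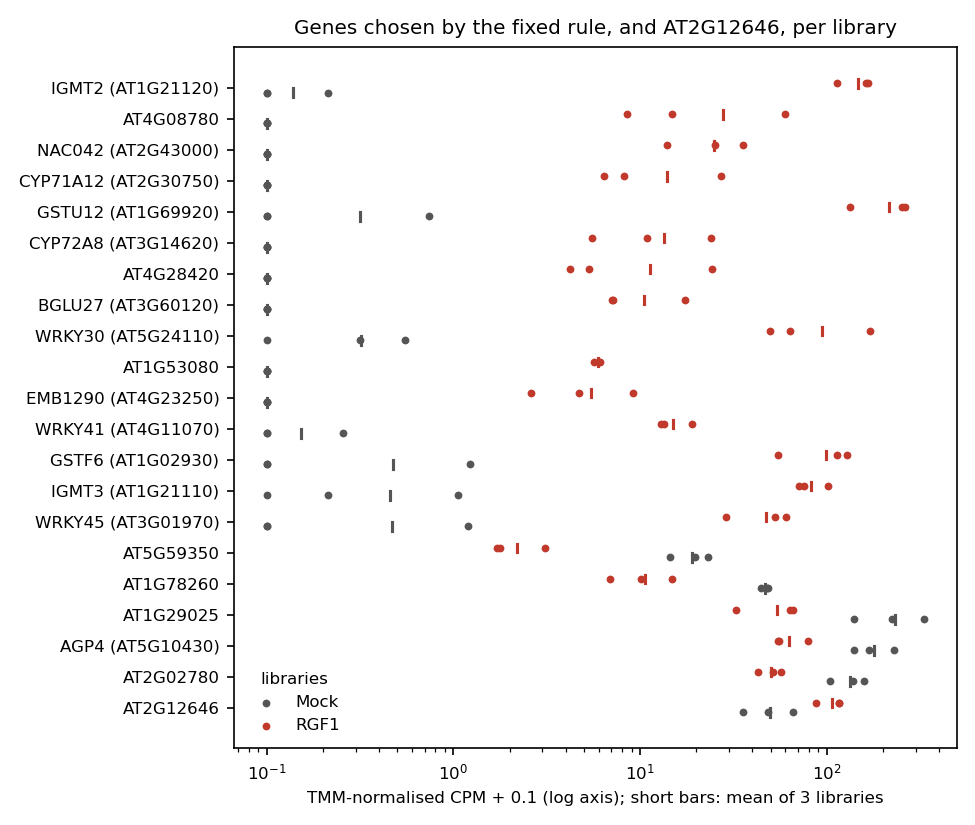
TMM-scaled CPM plus 0.1 on a log axis for the 20 genes chosen by the rule and for AT2G12646, with 1 point per library and short bars at the mean of 3 libraries. The RGF1 libraries (red) lie above the Mock libraries (grey) for the 15 genes that rose and below them for the 5 that fell.

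RITF1, the PLATZ-family transcription factor gene AT2G12646 (chromosome 2, 5166984 to 5169303), had 35.5, 48.4 and 65.9 CPM in the Mock libraries and 87.1, 116 and 116 CPM in the RGF1 libraries. Its log2 fold change was 1.09 ± 0.29 (SE) and did not pass the test over the tested genes (edgeR adjusted p = 0.182). With the replicate block AT2G12646 passed, at 1.12 and edgeR adjusted p = 0.0179, and with DESeq2 at 1.09 and adjusted p = 0.0429. The call with the block was lost whichever pair was left out, with edgeR adjusted p of 0.0546, 0.0515 and 0.0773 without pairs 1, 2 and 3. The gene was singled out by the study on these samples, so its direction here is not independent evidence.

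Glutathione S-transferases, which conjugate glutathione to reactive compounds, had the smallest camera p of the 28 lists. The 18 tested members had positive fold changes, with a median log2 fold change of 1.18, against 0.54 over all 31 tested genes named as glutathione S-transferases, and 5 passed the test over the tested genes, 9 adjusted over the list alone and 8 with the replicate block. Besides GSTU12 and GSTF6, the members that rose were GSTF2, GSTF7 and GSTU24, with log2 fold changes of 6.19, 5.17 and 2.12. The list rose as a set (camera adjusted p = 7.86e-14) and still did with an estimated correlation (camera adjusted p = 0.0287). The 31 genes were tested among 313 families built from product names, so their adjustment covers more sets. They rose with the preset correlation (camera adjusted p = 4.58e-06) but were not called with an estimated one (0.723). Without RGF1 replicate 1, 3 members passed, and of the 18 DESeq2 called 7 and limma voom 3. Among 15 stress-responsive ZAT, ERF, MYB and NAC factors, 4 rose, 7 adjusted over the list alone and 6 with the block. These were NAC042, the ethylene response factor genes ERF-1 and ERF5, with log2 fold changes of 1.91 and 2.24, and the zinc finger gene STZ (ZAT10) with 1.73. The list rose as a set with the preset correlation (camera adjusted p = 1.34e-07), but not with an estimated one (camera adjusted p = 0.362). Without Mock replicate 2 or RGF1 replicate 1, 1 and 2 of these factors passed, and of the 15 DESeq2 called 7 and limma voom 5. The fixed list of WRKY factors and markers of pattern-triggered immunity does not hold WRKY30, WRKY41 and WRKY45, named above. Of its 11 tested members, 0 passed in edgeR over the tested genes, 3 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 0. Adjusted over the list alone 3 passed, and the same number with the block. WRKY53, WRKY40 and WRKY33 had log2 fold changes of 1.88, 1.205 and 1.33. This list rose with the preset correlation (camera adjusted p = 0.0317), with an adjusted p = 0.818 for an estimated correlation and 0.0975 without the low-count filter. Of 36 tested genes whose product is named WRKY DNA-binding protein, 2 were called higher and 4 with the block, and their median log2 fold change was -0.12. Without Mock replicate 3, RGF1 replicate 1 or RGF1 replicate 2 the camera adjusted p of the WRKY list was 0.153, 0.0981 and 0.0718. In fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, the glutathione S-transferases and the stress-responsive factors passed (fry adjusted p of 0.00116 and 0.0433) and the WRKY list did not (0.592). Among lists that camera did not call, the mixed fry test, in which members may move either way, passed for meristem regulators (adjusted p = 0.00326), hypoxia genes (0.00475), auxin transporters (0.00560), jasmonate genes (0.0167), peroxidases (0.0223) and CDK inhibitors (0.0439). It did not pass for the other lists that camera did not call.

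**Figure D3:**
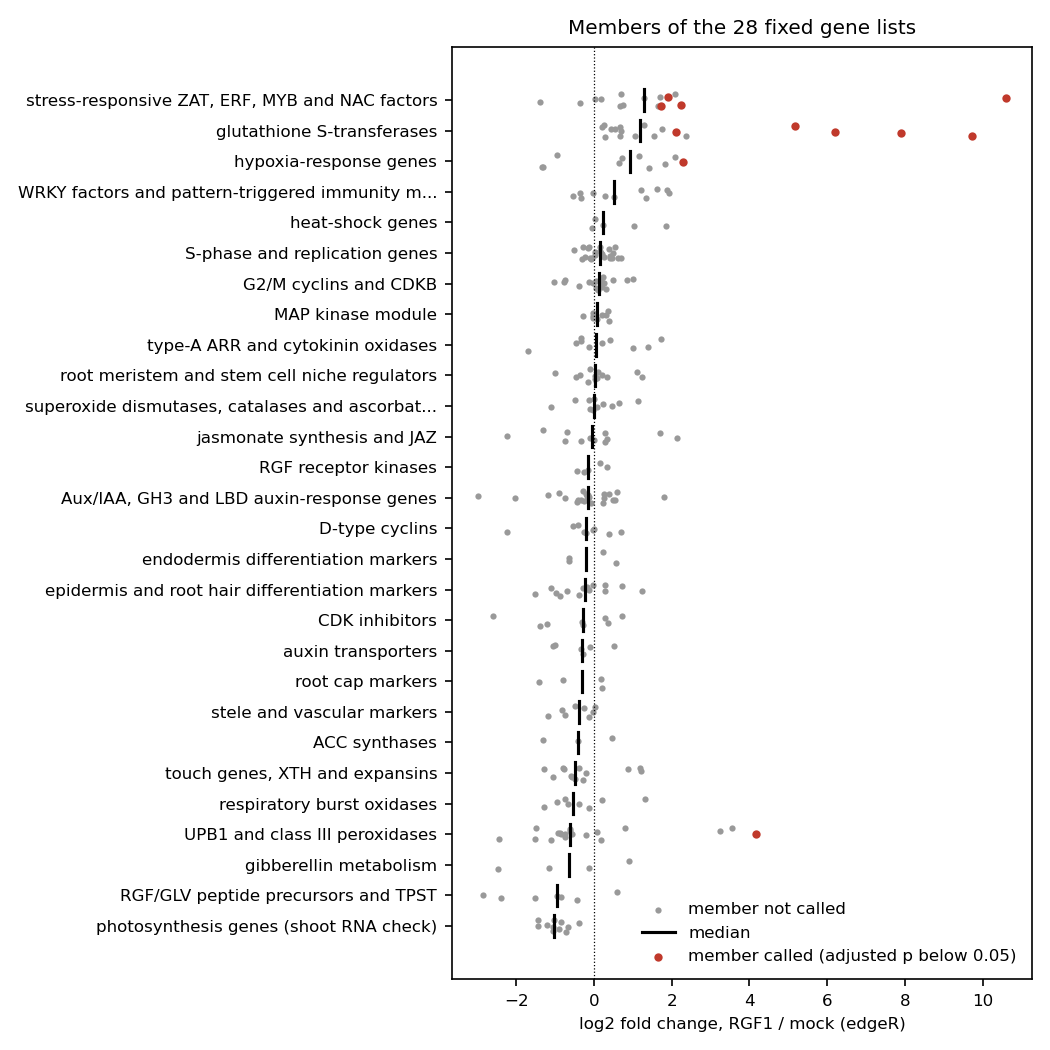
Log2 fold change (RGF1 over mock, edgeR) of each tested member of the 28 gene lists, ordered by list median (black bar). Red points are members with an adjusted p below 0.05, of which the glutathione S-transferases have 5 and the stress-responsive factors 4.

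Of the lists of genes that make or remove reactive oxygen species, only the peroxidase list held a called gene, and camera called none as a list. The fixed peroxidase list does not hold the peroxidase gene AT4G08780, named above. Of 38 tested genes whose product is named peroxidase, 2 were called higher, and with the block 4 were higher and 1 lower. Their median log2 fold change was -0.23. Of 19 tested members of the list of UPB1 and class III peroxidases, AT5G39580 rose with a log2 fold change of 4.16 ± 0.63 (SE) and edgeR adjusted p = 0.00741, 4 passed adjusted over the list alone, and with the block 2 were called higher and 1 lower. The list was not called in one direction as a set (camera adjusted p = 0.938), but it passed the mixed test of fry, which lets members move either way (adjusted p = 0.0223). The oxidase gene RBOHD, which produces apoplastic superoxide, had a log2 fold change of 1.32 ± 0.30 (SE) and edgeR adjusted p = 0.0839, passed adjusted over its list alone, and passed with the block (edgeR adjusted p = 0.0286). The 8 respiratory burst oxidases had a median log2 fold change of -0.53, while camera placed them higher, with adjusted p = 0.938. The 11 superoxide dismutases, catalases and ascorbate peroxidases had a median log2 fold change of 0.01 (camera adjusted p = 0.796). Among 10 hypoxia-response genes 1 rose, the haemoglobin gene HB1, with a log2 fold change of 2.28 ± 0.39 (SE) and edgeR adjusted p = 0.0165, and the list was not called (camera adjusted p = 0.0788).

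The lists of 24 of the 28 groups held 0 called genes in edgeR among their 241 distinct tested members, of which 27 had an unadjusted p under 0.05, DESeq2 called 4, limma voom 1 and the block fit 6. Of these lists, the RGF peptide precursors with the sulfotransferase TPST were lower as a set over 7 tested members (camera adjusted p = 0.0337), which did not hold with an estimated correlation (adjusted p = 0.442) in fry (adjusted p = 0.0612), with limma voom (0.220), with GC content and length offsets (0.190) or without the low-count filter (0.0975). The precursor genes RGF7 and RGF1 itself had log2 fold changes of -2.86 ± 1.00 and -2.38 ± 1.04 (SE). Without Mock replicate 3, RGF1 replicate 1, RGF1 replicate 2 or RGF1 replicate 3 the camera adjusted p of this list was 0.131, 0.0981, 0.0718 and 0.0888. The 5 RGF receptor kinases and the 9 genes of the MAP kinase module were not called as lists, with camera adjusted p of 0.865 and 0.683. Among 13 root meristem and stem cell niche regulators (camera adjusted p = 0.796), AIL6, known as PLETHORA 3, had a log2 fold change of 1.11 ± 0.22 (SE) and edgeR adjusted p = 0.0533, and passed adjusted over the list alone and with the block (edgeR adjusted p = 0.00295). DESeq2 and limma voom each called 1 gene of this list, AIL6. PLT1 and PLT2, which set meristem size, had log2 fold changes of -0.35 ± 0.51 and 1.23 ± 0.50 (SE). Of the 13 regulators, 2 were higher and 1, not named here, was lower at an unadjusted edgeR p under 0.05.

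Cell cycle genes were not called in either direction. The 18 G2/M cyclins and B-type CDKs, the 24 S-phase and replication genes, the 9 D-type cyclins and the 8 CDK inhibitors had camera adjusted p of 0.683, 0.374, 0.683 and 0.203. Their median log2 fold changes were 0.14, 0.15, -0.20 and -0.29. Among the hormone lists, 2 of 6 auxin transporters, PIN7 and PIN3, were lower adjusted over the list alone, with log2 fold changes of -0.999 ± 0.29 and -1.06 ± 0.35 (SE), and the list was not called (camera adjusted p = 0.203). The 24 Aux/IAA, GH3 and LBD genes (camera adjusted p = 0.683), the 12 genes of jasmonate synthesis and JAZ (0.938), the 3 ACC synthases (0.648) and the 4 gibberellin genes (0.203) were not called. The 10 type-A response regulators and cytokinin oxidases were not called either (camera adjusted p = 0.938), but ARR3 passed with the block, with a log2 fold change of 1.72 and edgeR adjusted p of 0.523 without the block and 0.0462 with it. The 5 heat-shock genes and the 13 touch, XTH and expansin genes had camera adjusted p of 0.938 and 0.796.

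Markers of other root tissues were not called as lists: the 4 root cap markers, the 14 epidermis and root hair markers, the 8 stele markers and the 4 endodermis markers had camera adjusted p of 0.374, 0.654, 0.203 and 0.807. Their median log2 fold changes were -0.30, -0.23, -0.38 and -0.20, with 2, 10, 7 and 2 members below 0, so a fall is not excluded. Photosynthesis genes, included as a check for shoot RNA, were lower as a set over 11 tested members (camera adjusted p = 0.0288) with a median log2 fold change of -1.02, and the call was lost with an estimated correlation (adjusted p = 0.927) and in fry (adjusted p = 0.858). Their summed CPM was 1333, 263 and 696 in the Mock libraries and 454, 57.5 and 729 in the RGF1 libraries. Without Mock replicate 1, Mock replicate 3 or RGF1 replicate 2 the camera adjusted p of the photosynthesis list was 0.356, 0.131 and 0.763. The chloroplast genome held 2.50%, 1.43% and 1.61% of the counts in the Mock libraries and 1.35%, 0.986% and 1.41% in the RGF1 libraries.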

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

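The fits without a pair of libraries and with the block scaled by total counts were chosen after seeing the data, and the other alternatives were set before the data were examined. Without a low-count filter 176 genes were called higher and 46 lower and 3 lists were called, against 78, 5 and 5. DESeq2 called 234 higher and 81 lower, and camera was not run on it. Pairing the libraries with the replicate block gave 208 higher and 94 lower, with 78 and 5 genes shared with the fit without it, and with GC content and length offsets as well 210 and 79, with 3 lists. The lists lost with the block and offsets and without the filter were the peptide precursors and the WRKY factors. The block scaled by total counts gave 191 and 95. The share of called genes that were higher was 94.0%, 92.9% to 93.2% under the other scalings, 79.3% without the filter, 74.3% with DESeq2 and 68.9% with the block. Leaving out 1 library gave 39 to 113 genes higher, 1 to 5 lower and 2 to 6 lists, and leaving out 1 pair under the block gave 116 to 221 higher and 39 to 130 lower: 204 and 60 without pair 1, 221 and 130 without pair 2, and 116 and 39 without pair 3. RITF1 (log2 fold change 1.09) passed with DESeq2 (1.09), with the block (1.12, or 1.09 scaled by total counts) and with the block and offsets (1.15), and leaving out 1 library gave 0.90 to 1.34 without a call. Its adjusted p ranged from 0.0159 to 0.465 over the alternatives, and was 0.0515 to 0.0773 under the block without 1 pair. With an estimated correlation 1 list was called. The cause of these shifts was not tested, except that leaving out a library or pair leaves fewer samples. Over 21 settings the named genes kept direction and call in 371 results and lost the call in 49. There were 0 reversals, which the rule that the groups do not overlap made all but certain. AT4G23250 lost the call in 11 settings and AT1G53080 in 6. Apart from the genes and counts named with a block value, the replicate block changed no other call of a named gene or list. At totals of 5421243 to 9495012 counts, changes near 2-fold were mostly below detection in the simulation without the block.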

Other observations

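The tests in this part on families, pathways, neighbouring genes, composition, green tissue in the Mock sections, genes that differ between replicate numbers and the share of clock genes among these were chosen only after the result was seen, and so were the intervals over the 3 pairs and the genes named here. The genes that rose included 5 of the 15 tested genes of the pathway that makes tryptophan, the precursor of indolic defence compounds (Fisher's exact test, one-sided, adjusted p = 1.12e-08 over 2 pathways). They were ASA1, ASB1, TRP1, TSA1 and TSB1, with log2 fold changes of 1.95, 2.23, 2.03, 1.60 and 1.74. ASB1 has a copy, AT1G24807, that is 97.9% identical over 1104 bp, so that its count is uncertain. The set was higher by camera (adjusted p = 2e-07), also with an estimated correlation (adjusted p = 0.0103). Among 19 tested genes of sulfate assimilation and cysteine synthesis, which feed glutathione, 3 rose, and 7 were called higher with the block (Fisher's exact test without the block, one-sided, adjusted p = 8.94e-05). SERAT2;1, APR3 and APS1 had log2 fold changes of 2.51, 2.59 and 1.82, and the set was higher by camera (adjusted p = 2e-07), but not with an estimated correlation (adjusted p = 0.0958). Both pathways were picked after the result was seen, and the adjustment over 2 pathways does not cover that choice.

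Over 313 families built from product names, chitinases were over-represented among the genes called higher with the block, with 4 of 8 tested (Fisher's exact test, one-sided, adjusted p = 0.000244). They included AT2G43620 and AT4G01700, which rose without it too, with log2 fold changes of 5.60 and 2.92. Without the block chitinases (2 of 8) and class I glutamine amidotransferase-like genes (2 of 10) were not over-represented, with adjusted p = 0.0737 for both. With the block, glutathione S-transferases (10 of 31, adjusted p = 7.82e-10) and class I glutamine amidotransferase-like genes (4 of 10, adjusted p = 0.000479) were over-represented as well, and the glutathione S-transferases were so without it too (5 of 31, adjusted p = 9.34e-05). With the block and without pairs 1, 2 and 3, the genes called higher numbered 5, 3 and 2 for the chitinases, 10, 10 and 8 for the glutathione S-transferases and 4, 4 and 3 for the amidotransferase-like genes. Among the genes called lower with the block, the plasma membrane intrinsic proteins, which are water channels, stood out with 6 of 11 (adjusted p = 3.77e-09) and a median log2 fold change of -1.51. PIP1C went from 446, 226 and 264 CPM in the Mock libraries to 128, 126 and 122 CPM in the RGF1 libraries, and was not called without the block (edgeR adjusted p = 0.0657). Other members rest more on Mock replicate 1: PIP1A went from 671, 189 and 86.2 CPM to 96.4, 77.1 and 23.7 CPM and PIP2A from 525, 121 and 119 CPM to 124, 77.7 and 67.1 CPM, and both also differed between the replicate numbers (edgeR adjusted p of 0.00716 and 0.0281). Xyloglucan endotransglucosylases (3 of 17, adjusted p = 0.0172) and lipid-transfer proteins (3 of 20, adjusted p = 0.0190) were over-represented among the lower genes. Without the block edgeR and limma voom called 0 genes lower in these 3 families. Their genes lower at an unadjusted edgeR p under 0.05 numbered 8, 6 and 6, and DESeq2 called 3, 4 and 3. With the block and without pair 1, 2, 2 and 0 of them were called lower, without pair 2, 9, 5 and 8, and without pair 3, 2, 0 and 0. With an estimated correlation camera called none of these families, with adjusted p from 0.723 for the glutathione S-transferases to 0.986 for the other 5. The 78 genes that rose held 10 pairs of neighbours among the tested genes, such as GSTF6 with GSTF7 and UGT73B4 with UGT73B5. Random sets of 78 tested genes held 0.369 on average and at most 4 in 10000 sets. These sets were not matched for expression or gene family. The pairs include neighbours of the same family, such as IGMT2 and IGMT3, whose reads may be shared. The excess therefore does not separate position on the chromosome from family membership.

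The genes higher after RGF1 may reflect the peptide, which is the difference the design names, and technical accounts were set against it. The real grouping called 83 genes and the highest of the other 9 groupings 0, and with the block 302 against 0 in the other 3 groupings that part the 3 pairs, but with 1 of 10 splits as the smallest share, the splits are too few for a share under 0.05. Rougher handling or wounding of the RGF1 seedlings stays open, since the jasmonate list, predicted to rise by more than 0.5, had a median log2 fold change of -0.0450 and medians of 0.06, -0.70 and 0.74 in the 3 pairs (95% interval over pairs -1.76 to 1.83). Green tissue in the RGF1 sections predicted a rise of the photosynthesis list, whose median was -1.02. Its medians in the pairs were -1.66, -2.16 and 0.07, and their interval over pairs (-4.15 to 1.66) alone does not exclude a rise. In the same pairs the 78 genes rose, with median log2 differences of 3.06, 2.97 and 3.26. RGF1 replicate 2, where they lay above every Mock library, had the lowest summed photosynthesis CPM of the 6 libraries (57.5). These values argue against green tissue as the source of these 78 genes. A bias in GC content or transcript length is argued against by 84 genes higher after these trends were removed, 77 of them shared with the 78.

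For the genes lower after RGF1, GC content and length are argued against by 79 genes lower with the block after their trends were removed, 72 of them shared with the 94. Composition, in which strongly induced genes push the others down, is argued against by a median log2 fold change of -0.0427 over the tested genes with the block and scaling by total counts alone, which called 95 genes lower (-0.0476 to -0.0219 in the 3 pairs). More green tissue in the Mock sections stays open too, since the chloroplast share of the counts was lower in each pair, with a mean log2 ratio of -0.54 (interval over pairs -1.40 to 0.32), and photosynthesis genes were lower in 2 of 3 pairs. So does a smaller share of elongating and differentiating tissue in the RGF1 sections. The 18 tested epidermis and endodermis markers had a median log2 fold change of -0.23 with a bootstrap interval over genes of -0.66 to 0.23 and medians of -1.39, -0.25 and 0.48 in the 3 pairs, which does not exclude the fall of 0.5 that was predicted, so this and an effect of the peptide cannot be told apart for these genes.

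Libraries with the same replicate number deviated together, and 259 genes differed between the numbers under the block, of which 36 were also among the 302 called between RGF1 and mock under it and 2 among the 83 called without it. The flavonol synthase gene FLS1 had 123 and 293 CPM in Mock and RGF1 replicate 2 and 3.44 to 7.21 CPM in the other 4 libraries, and the clock gene LHY had 12.5 and 15.3 CPM in replicate 3 and at most 1.88 CPM in the others. Depth and trends with GC content or length are argued against by lowest same-number correlations of 0.249 after thinning and 0.225 after removing the trends. Harvest at different times of day may contribute: the mean same-number correlation of 14 clock genes was 0.594, at the 95.5th percentile of 1000 expression-matched random sets (95th percentile 0.589), and 4 of the 14 differed between the numbers against 1.52% of the other genes (Fisher's exact test, one-sided, p = 4.96e-05). Fisher's exact test treats the 14 genes as independent, but clock genes can vary together, so its p does not measure spread between samples. The labels give no time of harvest, and the design names no biological difference between the numbers.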
